A study of Mus musculus with 6 samples.

How the data were processed

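Whole testes of C57BL/6J mice aged 8 weeks were profiled by bulk RNA sequencing in 2 groups of 3 samples, wild type and KIFC1 knockout. Per the labels' protocols, total RNA was isolated with RNAiso Plus, libraries were made with a Hieff NGS MaxUp Dual-mode mRNA kit, and sequencing was done on a NovaSeq instrument. The submitters' processing notes name Trimmomatic, HISAT2 and HTSeq, and the mouse genome build mm10, without versions. The annotation release, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. Reads from a gene and its antisense partner, from overlapping genes or from near-identical copies therefore cannot be told apart in these values. Of 97 genes named by the rule below, 50 overlap another annotated gene on either strand and 28 overlap a tested one. Apart from the genes marked in the text, the levels of Mus81, Pou5f2, Cdc20, Sgo2a, Kif2a, Kifc3, Spaca4, Tssk6, Fscn3, Rsph9, Spag17, Hook1, Ropn1l and Alas2 are uncertain because they overlap a tested gene.

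The deposited files hold raw counts per gene, 1 file per sample, as whole numbers that the authors had not normalized. Each file lists 51826 Ensembl gene identifiers and 0 rows that name no gene. Symbols, coordinates, exon lengths and GC content were taken from GENCODE release M21 on GRCm38, the assembly that mm10 names, which matched 51633 identifiers and left 193 without a symbol. A total of 17151 genes had 0 counts in every sample. Library totals ran from 29274603 to 38703606 counts, so that 3 counts correspond to between 0.0775 and 0.103 counts per 1000000 counts (CPM), a floor that covers counting error only. No pair of samples of a group agreed within sampling noise: chi-square per degree of freedom between them ran from 16.4 to 150.2.

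The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM scaling and the filterByExpr filter, fitted to all 6 samples without covariates. Genes with a two-sided Benjamini-Hochberg adjusted p under 0.05 were called, and a second count took those that differed at least 2-fold. Log2 fold changes are knockout over wild type as edgeR's fit gives them, with a standard error (SE) computed from the fold change and the F statistic. A prior count of 2 was used for log2 CPM values only. CPM values are TMM-scaled. The labels do not say that the samples of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical.

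A set of 20 gene lists, holding 534 distinct genes of which 514 were tested, was written from textbook knowledge before the data were examined, as were the comparisons, the tests and the rule for named genes. That rule took Kifc1 and Kifc5b. It then took the 8 largest rises and the 8 largest falls among called genes with a mean of at least 1 CPM, no overlap between the groups and a name that is not a predicted or clone name. It also took the 2 members of each list with the smallest p, with up to 2 more as examples, and the 2 genes of chromosomes X and Y with the smallest p. Other genes named were chosen after their values were seen, and are marked so. Lists and chromosomes were tested with camera (limma 3.58.1) on log2 CPM with a preset correlation of 0.01, beside camera with an estimated correlation and fry. Benjamini-Hochberg adjustment ran over the 20 lists, and separately over both sex chromosomes. With an estimated correlation, it often gave many lists the same adjusted p, set by a list with a larger unadjusted p.

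Alternatives planned before the data were examined were DESeq2 size factors, library size alone, no expression filter, a filter of at least 1 CPM in 3 samples, the DESeq2 1.42.0 Wald test, a replicate block, an estimated set correlation, and each sample left out in turn. Added after the data were seen were offsets that remove each library's trend with GC content, or with GC content and exon length (splines with 5 degrees of freedom, fitted on 12751 genes with a mean log2 CPM above 2). Also added were fits without mitochondrial genes, without knockout samples 1 and 3, without knockout sample 2 and with the offsets, and with every library thinned to 29274603 counts.

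The count test was tested on simulated data for the knockout against wild-type comparison, with 100 genes changed 2-fold and 100 changed 4-fold. Without simulated trends, over 21045 genes, it recovered 21% of the 2-fold and 94% of the 4-fold changes, and 8 of its 123 calls were unchanged genes. With the GC and length trends of the real libraries simulated, over 20998 genes, 72 of 188 calls were unchanged genes, and with the offsets 13 of 125 were. The simulated trends came from the same splines that the offsets fit. Their removal therefore does not show how well the offsets remove real trends or spare real effects. In the simulated set test, 3% of 200 random lists had a p under 0.05. Samples were shuffled there separately within each gene, which removes correlation between genes, so this share does not cover correlated lists.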

Results

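The series title places the kinesin-14 motor KIFC1, which moves towards microtubule minus ends, in meiotic recombination and male fertility, and the design asks which testis transcripts differ when KIFC1 is knocked out. RNA was measured in whole testes of 8-week-old C57BL/6J mice, with 3 wild-type and 3 KIFC1 knockout samples. The wild-type libraries held 35153122, 38703606 and 29274603 counts and the knockout libraries 38169198, 32129093 and 34789757. Group values below are means ± SD of 3 samples in counts per 1000000 counts (CPM), and a positive log2 fold change is higher in knockout. Genes are said to rise or fall in these bulk values. Such values cannot tell a change of transcript level per cell from a change in the share of cell types.

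Kifc1 mRNA was nearly lost in every knockout sample. Kifc1 (ENSMUSG00000079553, chromosome 17, 33875659 to 33890661, minus strand, mm10, protein-coding) stood at 15.5, 16.1 and 14.7 CPM in wild type and at 0.326, 0.737 and 0.282 CPM in knockout. The group values were 15.5 ± 0.708 and 0.448 ± 0.251 CPM, a log2 fold change of -5.09 (SE 0.35, edgeR adjusted p = 0.00378), which left 2.9% of the wild-type level. The knockout libraries held 9 to 26 Kifc1 counts each, against 448 to 634 in wild type. Its close paralog Kifc5b (ENSMUSG00000024301, chromosome 17, 26917091 to 26932583) stood at 9.07 ± 0.568 CPM in wild type and 4.77 ± 1.84 CPM in knockout, with a log2 fold change of -0.93 (SE 0.28, edgeR adjusted p = 0.0744, DESeq2 adjusted p = 0.0182). With each library's trends with GC content and exon length removed, Kifc5b had a log2 fold change of -0.46 (SE 0.33, edgeR adjusted p = 0.46). Reads of these paralogs can be shared, so both the remaining Kifc1 counts and the Kifc5b level are uncertain.

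**Figure D1:**
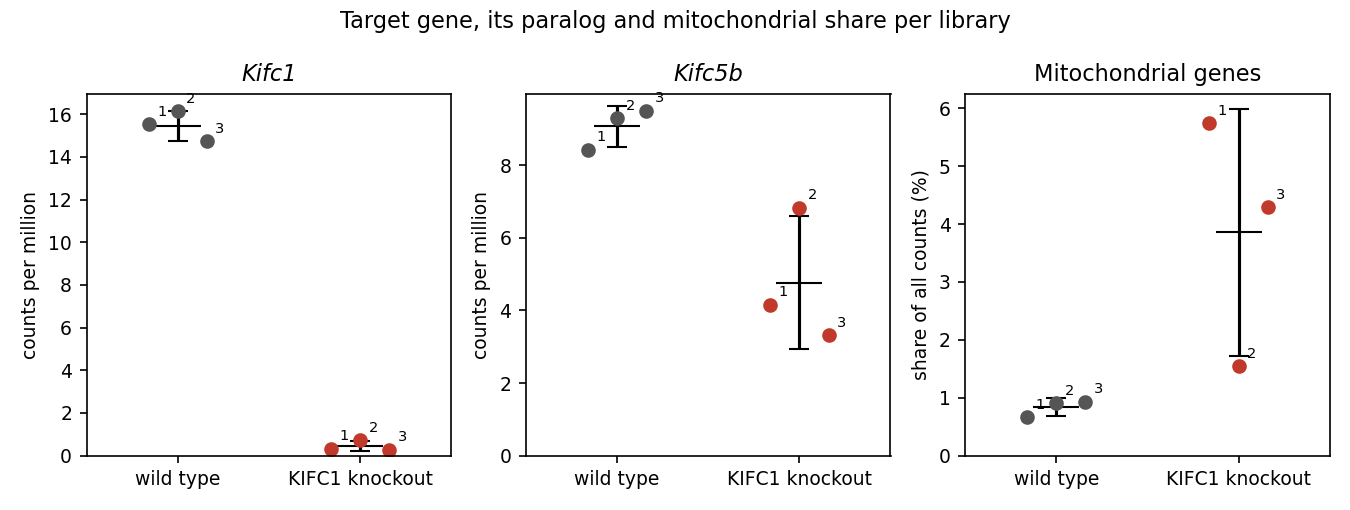
Kifc1 and Kifc5b in TMM-scaled CPM and the share of counts from mitochondrial genes in percent, for each wild-type and KIFC1 knockout library (points, numbered by replicate), with the mean (horizontal line) and SD (error bar) of 3. Kifc1 lies between 14.7 and 16.1 CPM in wild type and at or below 0.737 CPM in knockout, and the mitochondrial share is 1.54% in knockout 2 and 5.74% in knockout 1.

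Including Kifc1, 669 genes rose and 1101 fell among 21518 tested (edgeR quasi-likelihood test, adjusted p under 0.05), or 294 and 458 at a difference of at least 2-fold. Of the 1770 called genes, 1499 were protein-coding, and the median absolute log2 fold change was 0.94. The largest rises included the mitochondrial mRNAs mt-Atp6 (log2 fold change 4.30, SE 0.82), mt-Nd6 (3.53), mt-Nd2 (3.37), mt-Nd5 (3.32) and mt-Nd4l (3.25), and the mitochondrial tRNA gene mt-Te (3.37). The spans of mt-Atp6, mt-Nd6, mt-Nd5, mt-Nd2 and mt-Nd4l overlap neighbouring mitochondrial genes, so their separate levels are uncertain. Rnf26, which encodes a RING-type ubiquitin ligase, rose from 1.5 ± 0.696 to 19.2 ± 15.7 CPM (log2 fold change 3.67, SE 0.61, adjusted p = 0.0177), with 9.37, 10.9 and 37.2 CPM in knockout 1, 2 and 3. Its annotated span overlaps Mfrp and C1qtnf5, so reads there are uncertain. Within the protocadherin gamma cluster of chromosome 18, which encodes cell adhesion proteins, Pcdhga7 fell from 10.6 ± 5.74 to 0.534 ± 0.185 CPM (log2 fold change -4.30, SE 0.46, adjusted p = 0.0127). In the same cluster Pcdhga4 rose from 0.212 ± 0.0710 to 2.61 ± 1.07 CPM (log2 fold change 3.6, SE 0.46, adjusted p = 0.0161). Of 18 measured genes named as members of this cluster, 1 rose and 2 fell, the other being Pcdhgb6 (-1.90, SE 0.39), chosen after its values were seen. Their annotated spans overlap, which leaves their split uncertain.

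The other large falls were of Gjd3, a gap junction connexin gene, from 4.69 ± 1.39 to 0.866 ± 0.311 CPM (log2 fold change -2.44, SE 0.36, adjusted p = 0.0161) and of Metrn, which encodes the secreted protein meteorin, from 5.18 ± 1.19 to 1.15 ± 0.181 CPM (-2.17, SE 0.28), whose span overlaps Gm26694 and whose level is therefore uncertain. Pheta1, which encodes a protein of endosomal trafficking, fell from 15.7 ± 1.41 to 3.26 ± 2.41 CPM (-2.27, SE 0.44), with 1.684, 6.039 and 2.065 CPM in knockout 1, 2 and 3. Ppp1r18os (-2.54), an antisense gene that overlaps Ppp1r18, and the 7SL RNA copies Rn7s2 (-2.41) and Rn7s1 (-2.29) also fell, and are uncertain because of shared or opposite-strand reads. With trends of each library with GC content and exon length removed, the log2 fold changes were 4.02 for Rnf26, -1.52 for Gjd3, -1.64 for Metrn, -1.48 for Pheta1 and 3.65 for mt-Atp6. The count of calls moved by over 1.5 times with any library left out, to 5, 1 and 425 without wild type 1, 2 and 3 and to 1, 3149 and 327 without knockout 1, 2 and 3. It also fell to 11 once these trends were removed, while the genes with an edgeR unadjusted p under 0.05 went from 5830 to 4652.

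Called genes differed in base composition by direction. Genes that rose had a median exon GC content of 42.9%, genes that fell 56.3% and genes not called 49.2%. Of 1122 tested genes with at most 40% GC, 154 rose and 3 fell, and of 803 genes above 60% GC, 1 rose and 181 fell. Across 12751 genes, which are not independent replicates, the log2 fold change correlated with GC content at a Spearman rho of -0.533. The 3 wild-type libraries deviated from the mean of all libraries towards GC-rich genes (rho 0.262, 0.547 and 0.548) and the 3 knockout libraries towards AT-rich genes (rho -0.279, -0.695 and -0.131). With the trends removed, the 11 genes past the threshold were Kifc1 (-4.65), Pcdhga7 (-4.17), Pcdhga4 (3.79), Rps29 (-1.45), Cox5a (-1.10), Tmem64 (-1.14), Smim14 (-1.33), Micu3 (-1.36), Tmem239 (-1.27), 9330162G02Rik (-2.03) and 4932415D10Rik (1.43), given as log2 fold changes and chosen by this outcome. Rps29 encodes a small-subunit ribosomal protein, Cox5a a subunit of cytochrome c oxidase and Micu3 a regulator of mitochondrial calcium uptake.

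**Figure D2:**
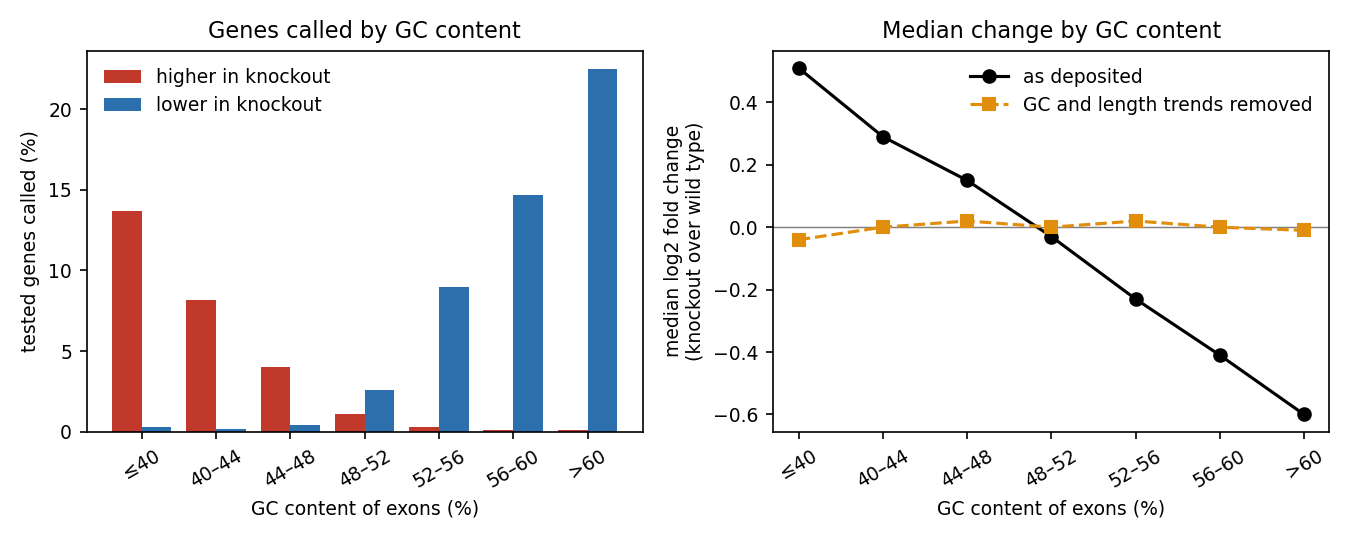
Left, share of tested genes called higher or lower in knockout (percent, bars) in 7 ranges of exon GC content; right, median log2 fold change of the same ranges in the counts as deposited (circles) and after removal of GC content and exon length trends (squares). The median falls from 0.51 at or below 40% GC to -0.60 above 60% GC, and lies between -0.04 and 0.02 once the trends are removed.

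Among meiotic prophase genes, several components of the chromosome axis and synaptonemal complex rose. Of 23 measured members of that list, 3 rose and 0 fell (6 and 0 adjusted over the list alone). They were Smc1b, the meiotic cohesin subunit, which rose from 121 ± 11.6 to 251 ± 22.6 CPM (log2 fold change 1.05, SE 0.14, adjusted p = 0.0161), Sycp2 of the lateral element (0.94, SE 0.17, adjusted p = 0.0201) and Sycp1, the transverse filament protein (0.90, SE 0.17, adjusted p = 0.0214). The list had a median log2 fold change of 0.13 and did not pass the set test (camera adjusted p = 0.186), and with the trends removed the median was -0.01, the tested direction turned (camera adjusted p = 0.745), and 1 gene was higher and 0 lower adjusted over the list alone. Of 43 recombination genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone). Ankrd31, which takes part in placing meiotic double-strand breaks, rose from 31.4 ± 4.48 to 54.5 ± 5.86 CPM (0.80, SE 0.17), the helicase gene Blm rose (0.73, SE 0.17), and Mus81, a nuclease of a minor crossover pathway, fell from 47.8 ± 10.8 to 22.2 ± 5.01 CPM (-1.11, SE 0.23, adjusted p = 0.0272). Mlh3, of the main crossover pathway, was at 25.2 ± 7.76 and 13.5 ± 0.155 CPM (-0.90, SE 0.24, adjusted p = 0.0545). The recombination list had a camera adjusted p of 0.77. With the trends removed its tested direction also turned (camera adjusted p = 0.146), and 0 genes passed adjusted over the list alone. Sycp2 and Sycp1 have 36.1% and 35.6% GC, and their log2 fold changes were 0.16 and 0.12 with the trends removed, against 0.67 for Smc1b, 0.39 for Ankrd31, 0.43 for Blm, -0.74 for Mus81 and -1.14 for Mlh3.

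Of 24 pachytene spermatocyte genes, 2 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.713). Brdt, the testis bromodomain protein gene, rose from 195 ± 11.7 to 306 ± 18.6 CPM (log2 fold change 0.65, SE 0.13). Mybl1, which encodes the A-MYB transcription factor of pachytene cells, rose (0.71, SE 0.15), and the POU-domain gene Pou5f2 fell (-0.92, SE 0.17). Of 31 genes of meiotic division and the spindle assembly checkpoint, 1 rose and 2 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.805). Cdc20, an activator of the anaphase-promoting complex, fell from 219 ± 33.3 to 91.1 ± 20.8 CPM (-1.27, SE 0.20, adjusted p = 0.0161), Espl1, which encodes separase, fell from 181 ± 9.05 to 113 ± 1.84 CPM (-0.68, SE 0.13, adjusted p = 0.0206), and the cohesin protector Sgo2a rose (0.61, SE 0.16). Of 41 kinesins, 4 rose and 2 fell (6 and 3 adjusted over the list alone, camera adjusted p = 0.765). Apart from Kifc1 they included Kif20b (0.93, SE 0.19) and Kif2a (0.68, SE 0.14), which rose, and the minus-end motor Kifc3, which fell (-0.66, SE 0.13). With the trends removed, the log2 fold changes were 0.48 for Brdt, 0.18 for Mybl1, -0.70 for Pou5f2, -0.92 for Cdc20, -0.47 for Espl1, 0.10 for Sgo2a, 0.38 for Kif20b, 0.33 for Kif2a and -0.17 for Kifc3. Adjusted over the list alone, 0 pachytene genes were then higher and 1 lower, and 1 division gene higher and 3 lower. Among kinesins 0 were higher and 1, Kifc1, was lower.

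Spermatid genes moved in both directions. Of 31 round spermatid and acrosome genes, 4 rose and 5 fell (6 and 6 adjusted over the list alone, camera adjusted p = 0.765). The acrosomal genes Eqtn (53.1 ± 5.29 to 113 ± 12.2 CPM, log2 fold change 1.09, SE 0.15) and Spaca7 (0.95, SE 0.16) rose, while Spaca3 (-1.07, SE 0.21) and Spaca4 (-1.07, SE 0.22) fell. Of 35 genes of elongating spermatids and nuclear condensation, 2 rose and 5 fell (2 and 11 adjusted over the list alone), with a median of -0.18 and a camera adjusted p of 0.185. The kinase gene Tssk6 fell from 673 ± 33.7 to 309 ± 79.8 CPM (-1.12, SE 0.19, adjusted p = 0.0182), as did Fscn3 (-0.76, SE 0.15) and Gpx4, the phospholipid peroxidase of the sperm midpiece (-0.88, SE 0.19). Smcp, of the sperm mitochondrial capsule, rose from 1781 ± 205 to 6350 ± 3686 CPM (1.83, SE 0.44), with 7584, 2206 and 9260 CPM in knockout libraries 1, 2 and 3, whose mitochondrial genes held 5.74%, 1.54% and 4.29% of counts. With the trends removed the median of this list was 0.03, its tested direction turned (camera adjusted p = 0.844), and 2 genes were higher and 1 lower adjusted over the list alone. The log2 fold changes were then 0.83 for Eqtn, 0.95 for Spaca7, -0.70 for Spaca3, -0.50 for Spaca4, -0.38 for Tssk6, -0.51 for Fscn3, -0.38 for Gpx4 and 1.87 for Smcp.

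Of 50 flagellum genes, 3 rose and 2 fell (6 and 3 adjusted over the list alone, camera adjusted p = 0.612). Fsip2 of the fibrous sheath (log2 fold change 0.95, SE 0.15) and the central apparatus genes Spef2 (0.73, SE 0.14) and Spag17 (0.68, SE 0.15) rose, and the radial spoke gene Rsph9 fell from 92.3 ± 21.2 to 42.1 ± 10.5 CPM (-1.13, SE 0.23). With the trends removed, their log2 fold changes were 0.15, 0.34, 0.42 and -0.88. Of 35 genes of the manchette and its transport, 4 rose and 1 fell (9 and 4 adjusted over the list alone, camera adjusted p = 0.394). Hook1, a manchette linker, rose from 255 ± 9.31 to 421 ± 3.23 CPM (0.72, SE 0.13, adjusted p = 0.0186), the transport gene Ift74 (0.81, SE 0.15) and the dynein adaptor gene Bicd1 (1.05, SE 0.25) rose, and Ropn1l fell (-0.62, SE 0.15). These 4 genes had log2 fold changes of 0.28, 0.48, 0.40 and -0.22 with the trends removed, when 0 flagellum and 0 manchette genes passed adjusted over the list alone. Of 27 piRNA pathway genes, 1 rose and 3 fell (2 and 4 adjusted over the list alone, camera adjusted p = 0.336). Pld6, a mitochondrial nuclease of piRNA maturation, fell from 83.3 ± 8.73 to 40.9 ± 6.19 CPM (-1.03, SE 0.17, adjusted p = 0.0168), with Rpap1 (-0.88, SE 0.15) and Tex19.1 (-0.78, SE 0.19), against -0.56, -0.56 and -0.52 with the trends removed. Rpap1 counts on the list as written, but encodes an RNA polymerase II-associated protein, so its fall is not read as one of the pathway. The piRNA list, with Rpap1 left in, passed the set test with the trends removed (camera adjusted p = 0.0464, median -0.16). With an estimated correlation its adjusted p was 0.836 (unadjusted p = 0.351), and 0 of its genes passed adjusted over the list alone. Of 23 spermatogonial genes, 0 rose and 1 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.765). That gene was Sohlh1, a transcription factor gene of differentiating spermatogonia, at 3.53 ± 0.417 and 1.61 ± 0.413 CPM (-1.14, SE 0.28, adjusted p = 0.0423), and the median (0.04) and the tested direction (lower) of the list differed in sign. With the trends removed, Sohlh1 had a log2 fold change of -0.63, and the list a median of -0.01 and the upward direction (camera adjusted p = 0.745).

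**Figure D3:**
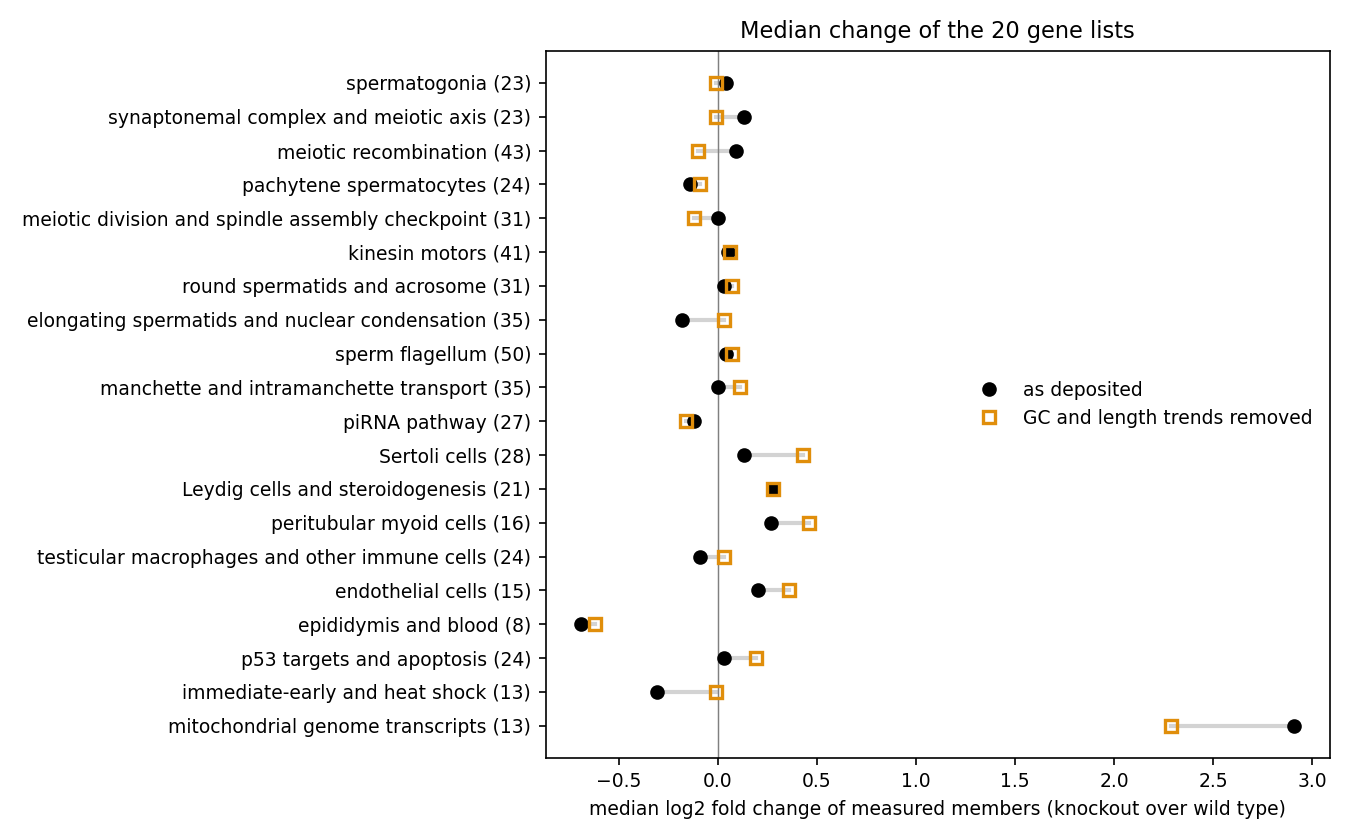
Median log2 fold change, knockout over wild type, of the measured members (number in brackets) of each of 20 gene lists in the counts as deposited (circles) and after removal of GC content and exon length trends (squares). The mitochondrial list lies at 2.91 and 2.29, and the elongating spermatid list moves from -0.18 to 0.03.

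Few somatic cell markers passed the test. Of 28 Sertoli cell genes, 2 rose and 0 fell (2 and 0 adjusted over the list alone), namely the homeobox gene Rhox8 (13.7 ± 0.665 to 27.5 ± 1.12 CPM, log2 fold change 1.01, SE 0.15, adjusted p = 0.0161) and the tight junction gene Tjp1 (1.0, SE 0.23). Of 21 Leydig cell and steroidogenesis genes, 1 rose and 0 fell (0 and 0 adjusted over the list alone), Akr1cl (0.87, SE 0.22). Cyp17a1, which encodes an enzyme of androgen synthesis, was at 228 ± 108 and 488 ± 109 CPM (1.10, SE 0.36, adjusted p = 0.0902). Wild type 1, 2 and 3 had 104, 301 and 278 CPM of it. None of 16 peritubular myoid, 24 macrophage and other immune, and 15 endothelial genes was called by edgeR, also adjusted over the list alone. At an unadjusted p under 0.05, 3 myoid genes were higher and 1 lower, 1 immune gene higher and 2 lower, and 2 endothelial genes higher and 3 lower, and DESeq2 called 2, 1 and 2 genes of these lists. The camera adjusted p values were 0.199 for Sertoli, 0.191 for Leydig, 0.336 for myoid and 0.765 for both immune and endothelial cells. Without wild type 1 they were 0.421 for Sertoli, 0.48 for Leydig and 0.713 for myoid cells, and without knockout 1 they were 0.489, 0.48 and 0.581. Leaving out any other single sample gave lower values for these 3 lists. With the trends removed, the Sertoli (median 0.43, adjusted p = 0.00076), Leydig (0.28, adjusted p = 0.0446) and myoid lists (0.46, adjusted p = 0.0131) passed the set test. With an estimated correlation each had an adjusted p of 0.836, at unadjusted p values of 0.234, 0.419 and 0.266. Adjusted over the list alone, 7 myoid genes were then higher and 1 lower, 4 Sertoli genes higher and 0 lower, and 0 genes of the Leydig, immune and endothelial lists passed. Rhox8, Tjp1, Akr1cl and Cyp17a1 then had log2 fold changes of 1.06, 0.82, 0.70 and 1.13. Of 8 genes of epididymis and blood, 0 rose and 1 fell (0 and 1 adjusted over the list alone, camera adjusted p = 0.0953), the erythroid gene Alas2 (22.1 ± 1.38 to 11.3 ± 1.25 CPM, -0.96, SE 0.17, or -0.77 with the trends removed). That list passed the set test with the trends removed (median -0.62 from -0.69, camera adjusted p = 0.0464). With an estimated correlation its adjusted p was 0.836 (unadjusted p = 0.185).

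All 13 protein-coding mRNAs of the mitochondrial genome rose, also adjusted over the list alone, with log2 fold changes from 0.88 for mt-Co3 to 4.30 for mt-Atp6 and a median of 2.91. mt-Co2, a cytochrome c oxidase subunit gene, stood at 723.5 ± 86.0 CPM in wild type and 3266 ± 1629 CPM in knockout (2.17, SE 0.37, adjusted p = 0.0177). Mitochondrial genes held 0.661%, 0.912% and 0.935% of counts in wild type and 5.74%, 1.54% and 4.29% in knockout. The shares of 0.84% ± 0.15 and 3.86% ± 2.13 gave a two-sided exact permutation p of 0.1, the smallest that 3 against 3 samples allow. The list passed the set test (camera adjusted p = 5.09e-08), but not with an estimated correlation (adjusted p = 0.896), and fry gave an adjusted p of 0.274. Reads of mt-Co2 and mt-Nd4l were counted in nearly equal number at the nuclear copies Gm28661 and Gm10222 (ratios between 1.001 and 1.034), so these levels are uncertain.

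Of 24 p53 target and apoptosis genes, 0 rose and 1 fell (0 and 1 adjusted over the list alone, camera adjusted p = 0.805). That gene was Bax, a promoter of apoptosis, at 7.61 ± 0.429 and 3.94 ± 0.564 CPM (log2 fold change -0.95, SE 0.21, adjusted p = 0.0315, or -0.41 with the GC content and length trends removed). None of 13 immediate-early and heat shock genes was called by edgeR over all genes, 3 were lower adjusted over the list alone, 1 was higher and 5 were lower at an unadjusted p under 0.05, and DESeq2 called 3. That list had a median log2 fold change of -0.31 and a camera adjusted p of 0.336. With the trends removed its median was -0.01, its tested direction turned upward (camera adjusted p = 0.618), and 0 genes passed adjusted over the list alone.

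The sex chromosomes, which are silenced in male meiosis, were compared with all other genes. On chromosome X, 83 of 986 tested genes rose and 4 fell, with a median log2 fold change of 0.30. The camera adjusted p was 1.34e-06, or 0.0923 with an estimated correlation, and the fry adjusted p was 0.0292. On the autosomes 541 of 20123 genes rose and 1096 fell, with a median of -0.02. Cylc1, which encodes a protein of the sperm head cytoskeleton, rose from 35 ± 4.66 to 125 ± 28.6 CPM (1.84, SE 0.20, adjusted p = 0.0127), and Rpgr, a ciliary gene, rose from 27.2 ± 2.33 to 58.3 ± 1.63 CPM (1.10, SE 0.14, adjusted p = 0.0161), with a span that overlaps Srpx and a level that is therefore uncertain. On chromosome Y, 25 of 333 genes rose and 0 fell, while the median was -0.06, the mean 0.11 and the tested direction upward (camera adjusted p = 0.0904). Rbm31y rose from 10.7 ± 0.626 to 17.7 ± 0.625 CPM (0.73, SE 0.16), and the multicopy gene Sly rose (1.18, SE 0.28) with reads shared among copies, which makes its level uncertain. The tested genes of chromosomes X and Y had a median GC content of 45.2% and 44.4%, against 49.8% on the autosomes. With the GC content and length trends removed, the log2 fold changes were 1.21 for Cylc1, 0.82 for Rpgr, 0.44 for Rbm31y and 0.72 for Sly. The median was then 0.11 on chromosome X (camera adjusted p = 0.0106) and -0.25 on chromosome Y, where the tested direction turned (camera adjusted p = 0.000133). With an estimated correlation the adjusted p was 0.323 for both chromosomes, and the fry adjusted p was 0.183 for X and 0.141 for Y. With the GC content trend alone removed, chromosome X had a median of 0.06 (adjusted p = 0.0539).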

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

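The trend offsets and the fits without mitochondrial genes, without knockout 1 and 3 together, without knockout 2 with offsets, and with thinned libraries were chosen after the data were seen. The cause of the differences below was not tested unless named. Against 669 genes higher and 1101 lower, DESeq2 size factors, library size alone, at least 1 CPM in 3 samples, no mitochondrial genes and thinned libraries gave counts within 1.5 times. Testing 34675 genes without a filter gave 370 and 640, and the DESeq2 Wald test 1542 and 1763 (532 at least 2-fold higher). With 1 sample left out, counts ranged from 0 to 1457 higher and 1 to 1692 lower, or 0 to 647 and 1 to 724 at least 2-fold. They were 2 and 3 without wild type 1, 0 and 1 without wild type 2, 108 and 317 without wild type 3, 0 and 1 without knockout 1, 1457 and 1692 without knockout 2, and 85 and 242 without knockout 3. Where edgeR called 0 higher, unadjusted p values under 0.05 numbered 4286 without wild type 2 and 4030 without knockout 1. GC offsets left 2 and 5 calls and GC and length offsets 2 and 9, with the same counts at least 2-fold. Without knockout 1 and 3 there were 0 and 2, all at least 2-fold (4371 at an unadjusted p under 0.05), in a fit that assumes the lone knockout sample varies like wild type. Kifc1 then had a log2 fold change of -4.38 and was not called, while its other alternatives ran from -4.65 to -5.65, all called. Without knockout 2 and with offsets there were 1489 and 1319 calls (634 at least 2-fold higher).

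Replicate numbers did not pair the samples (r of -0.48, -0.12 and -0.14 between deviations of samples with the same number), and with the replicate block 8 genes were higher and 13 lower, all at least 2-fold. No sample correlated best with its own number in the other group. The block moved the epididymis and blood list to an adjusted p of 0.00609 (adjusted p = 0.907 with an estimated correlation).

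With an estimated correlation the mitochondrial list (adjusted p = 0.896) and chromosome X (0.0923) were not called, although chromosome X passed so without knockout 1 and 3 (0.035), and the mitochondrial list was called under all other alternatives. Ranks of the DESeq2 statistic called the synaptonemal complex list (0.0406) and the epididymis and blood list (0.0406). With 1 sample left out, adjusted p ranged from 0.0099 to 0.311 for epididymis and blood and from 0.0211 to 0.416 for elongating spermatids, with calls of the first without wild type 1 or knockout 2 and of the second without knockout 3 (adjusted p from 0.673 to 0.95 with an estimated correlation). GC offsets called piRNA (0.0467), Sertoli (0.00143), Leydig (0.0314), myoid (0.0174) and epididymis and blood (0.0314), and GC and length offsets gave 0.0464, 0.00076, 0.0446, 0.0131 and 0.0464. With an estimated correlation all 5 had an adjusted p of 0.777 under GC offsets and 0.836 under GC and length offsets. Without knockout 1 and 3 the synaptonemal complex (0.0348) and elongating spermatid (0.0244) lists were called. Without knockout 2 and with offsets piRNA (0.0298), Sertoli (0.0038), myoid (0.028) and epididymis and blood (0.0413) were. With an estimated correlation, adjusted p was 0.998 and 0.94 for the lists called in these 2 fits. Chromosome X was not called with GC offsets (0.0539) or without knockout 2 with offsets (0.105). Chromosome Y was called upward with library size alone (0.0441), the 1 CPM filter (1.1e-05), thinned libraries (0.0427), without knockout 1 and 3 (9.48e-07), and without wild type 1 (0.000157) or knockout 1 (0.00299), its range with 1 sample left out being 0.000157 to 0.654. It turned downward with GC offsets (7.48e-06), GC and length offsets (0.000133) and without knockout 2 with offsets (7.17e-05), with an adjusted p of 0.366, 0.323 and 0.347 with an estimated correlation, which also ended each upward call (0.163 to 0.704). Of 1715 values of 97 named genes under alternatives, 1134 kept direction and side of the threshold, 537 lost and 44 gained the call, and 0 reversed. Of 360 list values, 30 changed sign with neither value past the threshold. At this depth and spread, the simulated comparison without trends recovered 21% of 2-fold changes. With trends simulated it recovered 29%, or 25% with the offsets. The adjusted threshold depends on how many genes changed, which is unknown in the real samples, so these shares do not carry over directly.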

Other observations

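The nuclear respiratory chain and ribosomal protein sets, and the tests of explanations below, were chosen only after the result was seen. Nuclear genes of the respiratory chain lay on the other side of the mitochondrial genes. Of 80 measured nuclear-encoded subunits, 1 rose and 27 fell, with a median log2 fold change of -0.63 (camera adjusted p = 1.35e-12, adjusted p = 0.302 with an estimated correlation), while all 13 mitochondrially encoded mRNAs rose. Cox5a fell from 160 ± 9.96 to 81.6 ± 5.64 CPM (-0.97, SE 0.14), and Uqcrq, a complex III subunit gene, fell (-1.35, SE 0.26). With GC content and length trends removed, the median of these subunits was -0.45 (camera adjusted p = 4.81e-13, adjusted p = 0.205 with an estimated correlation). The fry adjusted p of the subunits was 0.0424 in the deposited counts and 0.0187 with the trends removed. Of 81 ribosomal protein genes, 0 rose and 17 fell, with a median of -0.60 and of -0.39 with the trends removed. The camera adjusted p values were 2.9e-11 and 8.35e-10, or 0.302 and 0.318 with an estimated correlation, and the fry adjusted p values 0.0691 and 0.107. Among them, Rps29 fell from 253 ± 28.0 to 79.8 ± 12.5 CPM (-1.67, SE 0.17).

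The 1770 called genes followed GC content, and the direction of each library's GC trend separated the groups. Trends of GC content and exon length as the whole cause are argued against, as far as the offsets remove them. With both removed in all 6 samples, 99.7% of the called genes kept their sign, at a median absolute log2 fold change of 0.61 (median SE 0.186). The called genes were chosen in these same libraries. Over all 21518 tested genes, 909 then had an edgeR unadjusted p at or under 0.00411, that of the last call in the deposited counts. Trends that the offsets leave behind stay open. Without knockout 2 and with both trends removed, 1001 of the 1770 genes (56.6%) were called again, against 10 in all 6 samples. The fit without knockout 2 was chosen after the data were seen, and its libraries had also chosen the 1770 genes, so it cannot decide. Of the libraries left out singly, knockout 2 was the only one whose removal raised the calls, to 3149, with 1669 of the 1770 called again, so the 1001 rest on leaving out that library. In all 6 samples the offsets moved the median absolute log2 fold change of the called genes from 0.94 to 0.61 at a median SE of 0.189 and 0.186. Smaller differences and a stricter threshold both ended calls: 581 of the 1770 genes still passed the unadjusted p of the last call in the deposited counts, 0.00411, but 10 passed the adjusted threshold, which lay at an unadjusted p of 2.22e-05. As part of the cause, trends of the libraries and effects of the knockout cannot be told apart for the 1770 genes, since groups and trends coincide. A difference in depth is argued against by library totals that overlapped between the groups, at 29274603 to 38703606 counts in wild type and 32129093 to 38169198 in knockout. Thinning every library to the smallest left 1835 calls, but with such totals it could hardly end them.

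The 10 splits of 6 samples are too few for a share under 0.05: for calls, 1 of 10 splits reached the real count of 1770 (highest other 2). For calls of at least 2-fold, 1 of 10 reached 752 (highest other 2). For called lists 8 of 10 splits reached the real count of 1 (highest other 8), and for called chromosomes 9 of 10 reached 1 (highest other 2). Most other splits thus called as many lists or chromosomes as the real one. The number that passed the set test therefore does not set knockout and wild type apart.

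Mitochondrial mRNAs were higher in each knockout library than in any wild-type library, by unequal amounts. GC content and length trends as the whole cause are argued against by a median log2 fold change of 2.29 with both removed, from 2.91, at a median SE of 0.59 and 0.55. At 2.29 the list passed the threshold with the preset correlation (adjusted p = 9.11e-05), but not with an estimated correlation (adjusted p = 0.836), where it had not passed before either (0.896). None of the 13 was then called by edgeR over all genes, where the unadjusted p had to reach 2.22e-05, while 12 had an unadjusted p under 0.05 (8 at or under 0.00411) and were called adjusted over the list alone, and mt-Nd3 was at 0.12, where these trends stay open. An equal rise of all 13 mRNAs is argued against in knockout 1 and 3, where their spread (SD of log2 differences from wild type) was 1.15 and 1.06 against at most 0.41 in wild type, and stays open in knockout 2, at 0.31. RNA handling or library yield that differed between the groups cannot be told apart from the knockout, since no label records handling and the shares separate the groups with an exact permutation p of 0.1, the smallest possible.

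DNA of another strain kept around the Kifc1 allele may alter expression of its neighbours, as a hypothesis. Within 5 Mb of Kifc1 on chromosome 17, 17 of 225 tested genes (7.6%, exact 95% binomial interval 4.5% to 11.8%) had an unadjusted p under 0.01 with the trends removed, against 1621 of 19897 other autosomal genes (8.1%). The one-sided Fisher's exact p was 0.662, so no excess was found. A share of genes cannot exclude single altered neighbours. Ppp1r18os, among the largest falls, lies within this window, at 35860918 to 35866886.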
